A study of Mus musculus with 32 samples.

How the data were processed

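Small RNA libraries of mouse testis were made, per the labels' protocols, from total small RNAs of 19 to 40 nt or from RNA bound to MILI or MIWI2, the MIWI2 RNA being size-selected to 24 to 30 nt and the MILI RNA not. Per the submitters' processing notes, reads were mapped with Bowtie, whose version is not given, to mm10. Values deposited by the authors are counts: the reads of each distinct sequence in each library, without normalization, with 1 reported position and 1 annotation per sequence (per the file headers). The tables held 2910572 distinct sequences for newborn total RNA, 16415544 for 12 to 14 days and 31759458 for the IPs, of which 1620095 had no read in any library. For the Rosa26-pi construct the authors deposited expected counts, in which the reads of a sequence found at several positions are split between them; 414 of 15876 table lines (2.61%) held a value that was not a whole number. Those values were rounded to whole reads for the intervals. Of the 12 columns with values in that table, 6 matched the samples and 6 were not analysed here.

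Groups were taken from the sample titles: genotype, age and purification. Reads were summed, by annotation and strand relative to it, into features: repeat subfamilies, genes, miRNAs and structural RNAs. Each sequence was counted once, at its reported annotation, and reads without annotation entered the library totals only. They made up 2.29% to 4.96% of newborn total reads, 3.74% to 18.3% at 12 to 14 days, 21.5% to 28.1% of MILI and 15.5% to 19.5% of MIWI2 reads. In the 12 to 14 day set the library richest in them was replicate 1 of the wild type (13.3%) and of Tdrd12+/+ Exd1-/- (18.3%). Stated read lengths and bases at positions 1 and 10 were recomputed from every sequence and differed in 0 entries of each table. Gene positions were matched by symbol to an annotation of GRCm38.p6, the assembly of mm10, for 59 of 65 named genes.

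Counts per feature were compared with the quasi-likelihood F-test of edgeR 4.0.16 (robust, two-sided) in R 4.3.3, after its expression filter, with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. Library totals set the scale, without further factors, because TMM would centre away a change of piRNAs as a class in total RNA. IP values are shares of bound RNA, not amounts. The 9 libraries of 12 to 14 days shared 1 fit, as did the 6 MILI libraries, the 5 MIWI2 libraries and all 11 IP libraries for the interaction. The group of 1 library was taken to vary like the others. Feature lists were fixed before the data were examined, as were the comparisons, the main settings and most alternatives: young LINE1, older LINE1, IAP, other ERVK, MuLV and other ERV1, ERVL and MaLR, and SINE elements on each strand, the let-7 family, pluripotency and germ cell miRNAs, meiotic miRNAs, miRNAs of other testis cells, and rRNA and tRNA fragments. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again at an estimated one, and with fry. Class shares were compared between groups of 3 with exact two-sided permutation tests (scipy 1.17.1), whose smallest p is 0.10. No exact test was run on smaller groups. The piRNA window was 24 to 30 nt. Ping-pong overlaps were counted from sequences with 1 genomic position as the smaller of the reads on either strand, at each overlap of 1 to 20 nt. Shares of single libraries have 95% Clopper-Pearson intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and DESeq2 1.42.0 were also used.

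Named features followed a rule written in advance: in each comparison, of the features with an adjusted p under 0.05, a mean of at least 10 cpm and groups that did not overlap, the 10 with the largest fold in each direction. Added to them were Exd1, Tdrd12, L1Md_A, L1Md_T, L1Md_Gf, IAPEz-int, IAPLTR1_Mm, MERVL-int, MMERVK10C-int, B1_Mm, B2_Mm2 and the 2 to 4 members of each other list with the highest mean. The rule gave 1051 feature and comparison pairs. Those followed one by one are the 4 with the largest fold in each direction, Exd1, Tdrd12, L1Md_A, L1Md_T, IAPEz-int and MMERVK10C-int, a choice that does not look at their stability. Alternatives were TMM factors, TMM over miRNA features, DESeq2, no expression filter, a minimum mean of 10 cpm, reads of 24-30 nt, uniquely placed reads, a fit of the 2 groups alone and leaving out each library in turn. Added after the data were seen were library sizes without tRNA and rRNA reads, reads of at most 40 nt, leaving out the 2 wild-type libraries richest in albumin reads and leaving out the libraries richest in unannotated reads. Shares were recomputed over reads of 19 to 40 nt, over distinct sequences and with a window of 25 to 31 nt.

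The procedure was tested on simulated data with 100 changed features per fold size, too few to test the scaling. For the newborn total comparison (6202 features) it recovered 22 at 2-fold and 85 at 4-fold, with 7 false among 114 calls. For Tdrd12+/+ Exd1-/- against the wild type at 12 to 14 days (17705 features) it recovered 23 and 85, with 10 false of 118. For Tdrd12+/+ Exd1-/- against Tdrd12+/+ Exd1+/- it recovered 32 and 89 in MILI (25602 features; 15 false of 136) and 18 and 83 in MIWI2 (18950 features; 8 false of 109). For the lone Tdrd12+/- Exd1-/- MIWI2 library it recovered 5 and 49, with 2 false of 56. A planted share of 28.3% of 10-nt overlaps was found as 27.7%. Replicates differed by 4.56 to 85.8 times the variance that counting alone gives.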

Results

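Small RNAs were sequenced from testes of mice with mutations in Exd1 and Tdrd12, genes of the piRNA pathway, which silences transposons in the male germ line through small RNAs bound by PIWI proteins. Total small RNAs of newborn testes (day 0) came from Tdrd12+/- Exd1+/- and Tdrd12+/- Exd1-/- mice, with 3 libraries each. Total small RNAs of testes aged 12 to 14 days came from wild-type (Tdrd12+/+ Exd1+/+), Tdrd12+/+ Exd1-/- and Tdrd12+/- Exd1-/- mice, with 3 libraries each. At birth, small RNAs bound to the PIWI proteins MILI and MIWI2 were also purified by immunoprecipitation (IP) from Tdrd12+/+ Exd1+/-, Tdrd12+/+ Exd1-/- and Tdrd12+/- Exd1-/- testes. Each IP group held 2 libraries, except MIWI2 in Tdrd12+/- Exd1-/-, which held 1. A further 6 libraries, each without a replicate, measured MILI and MIWI2 small RNAs on an artificial piRNA precursor, Rosa26-pi, in Exd1+/+, Exd1+/- and Exd1-/- testes.

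Total libraries held 3364231 to 5117237 reads at birth and 11578090 to 18000254 at 12 to 14 days, MILI IP libraries 6042126 to 8571238 and MIWI2 IP libraries 5707593 to 7402580. Reads were summed per annotated repeat, gene or structural RNA and per strand, and levels are given in cpm, counts scaled to the reads of the library. The p-values measure the spread between these samples only, since the labels do not say whether replicates were separate animals or litters. Counting intervals and floors cover counting error alone.

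Small RNA reads on a gene do not measure its mRNA. Exd1 lies on chromosome 2 at 119516505 to 119547627 and Tdrd12 on chromosome 7 at 35466941 to 35537784 (GRCm38). At 12 to 14 days, sense Exd1 reads fell in Tdrd12+/+ Exd1-/- relative to the wild type, at 3.02 ± 0.791 against 5.36 ± 1.60 cpm (SD, n = 3 each), a log2 change of -0.82 ± 0.24 (SE) with an adjusted p of 0.0307. The counts were 63, 36 and 33 against 85, 70 and 128, so that reads from the Exd1 locus persisted in the mutant. The call was lost under TMM scaling (-0.40) and without wild-type replicate 3 (-0.56) or Tdrd12+/+ Exd1-/- replicate 2 (-0.66) or 3 (-0.78). In Tdrd12+/- Exd1-/- at that age, antisense Exd1 reads rose by 1.35 ± 0.31 on the log2 scale (adjusted p 0.0253), from counts of 14, 21 and 18 to 40, 53 and 35, and sense Exd1 reads did not pass (adjusted p 0.184). Sense Tdrd12 reads were higher in Tdrd12+/- Exd1-/- than in the wild type (0.88 ± 0.21, adjusted p 0.0309) and than in Tdrd12+/+ Exd1-/- (1.29 ± 0.22, adjusted p 0.0144), with counts of 56, 49 and 47 against 22, 32 and 34 and against 20, 18 and 16. The calls of antisense Exd1 and of sense Tdrd12 against the wild type were lost without any single one of the 6 libraries (1.19 to 1.49, and 0.73 to 0.98), and that of Tdrd12 between the mutants under TMM (1.04) and without any library but Tdrd12+/+ Exd1-/- replicate 1 (1.21 to 1.35). In the newborn total libraries Exd1 sense counts were 11, 13 and 7 in Tdrd12+/- Exd1+/- and 5, 3 and 7 in Tdrd12+/- Exd1-/-, below the filter for testing. In the MILI IP, Exd1 sense counts were 95 and 120 in Tdrd12+/+ Exd1+/-, 94 and 74 in Tdrd12+/+ Exd1-/- and 73 and 89 in Tdrd12+/- Exd1-/-, and neither gene passed in a MILI comparison.

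The newborn total libraries asked how small RNAs differ without EXD1 where 1 copy of Tdrd12 is missing. Antisense reads of young LINE1 families, retrotransposons that are still mobile in the mouse, fell in Tdrd12+/- Exd1-/- testes (n = 3 each). L1Md_A antisense reads averaged 432 ± 70.6 cpm against 1732 ± 161 in Tdrd12+/- Exd1+/- (SD), a log2 change of -2.004 ± 0.23 (SE; adjusted p 1.66e-15), and L1Md_T antisense reads changed by -1.80 ± 0.23 (adjusted p 6.11e-13). On the sense strand L1Md_A fell (log2 change -1.05), with the call lost among 24-30 nt reads (-0.76) and among uniquely placed reads (-0.52), and L1Md_T sense did not pass (adjusted p 0.935). Among endogenous retroviruses, IAPEz-int antisense reads fell (-1.25 ± 0.22, 788 ± 143.7 against 1872 ± 230.3 cpm), and MMERVK10C-int passed on neither strand (adjusted p 0.0585 and 0.119). IAPEz-int sense reads passed at -0.75 (adjusted p 0.0132), but the call was lost under TMM scaling (-0.43) and without Tdrd12+/- Exd1+/- replicate 2 (-0.80) or 3 (-0.59), or Tdrd12+/- Exd1-/- replicate 1 (-0.62) or 2 (-0.73). The major satellite GSAT_MM, a repeat of pericentromeric heterochromatin, fell to 20.5 ± 5.90 from 425 ± 63.6 cpm on the sense strand (-4.37 ± 0.30), with -4.35 on the antisense strand. LTRIS4B sense reads fell (-2.28), with the call lost among 24-30 nt reads (-0.75). The largest fold among the named features belonged to sense reads of the albumin gene Alb (chromosome 5, 90460870 to 90476602), with counts of 302, 333 and 388 in Tdrd12+/- Exd1+/- and 0, 3 and 0 in Tdrd12+/- Exd1-/-, a ratio of 345-fold with a 95% counting interval of 118 to 1674. The largest rise was that of initiator tRNA-Met-i, by 2.94 ± 0.27 (502 ± 99.8 against 65.7 ± 14.6 cpm), and tRNA-Arg-AGA rose by 1.90, the latter with the call lost among 24-30 nt reads (0.46). LTR10_RN antisense rose by 1.97 and L1MD3 sense by 2.14; both depended on read selection, since LTR10_RN did not pass among 24-30 nt (0.26) or uniquely placed reads (0.90) and L1MD3 turned lower there (-0.32 and -0.42).

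Of the members of the transposon lists that passed at birth, more fell than rose. The same libraries differed in hepatocyte reads (94 in Tdrd12+/- Exd1-/- against 2564 over 27 genes) and in reads over 40 nt (0.357% to 0.454% against 0.0206% to 0.140%). All 6 young LINE1 antisense features fell (median log2 change -1.72, under TMM scaling -1.42), against 3 of 6 on the sense strand, with 3 not passing. Of 25 IAP features, 10 fell on the sense strand (18 adjusted over the list alone) and 14 on the antisense strand (21 adjusted over the list alone), as did 11 of 20 other ERVK features on each strand (17 and 15 adjusted over the list alone). MuLV and other ERV1 elements fell in 9 of 21 sense and 5 of 20 antisense features, and ERVL and MaLR elements in 13 of 54 sense and 19 of 52 antisense features, where 2 rose. SINE features fell in 5 of 31 sense (1 under TMM) and 8 of 31 antisense cases. Older LINE1 elements were mixed, with 1 rising and 6 falling of 81 sense features and 3 rising and 13 falling of 87 antisense ones. None of the 16 let-7, 19 pluripotency and germ cell or 17 meiotic miRNA features passed, and 1 of 14 miRNAs of other testis cells fell. Of 59 rRNA and tRNA fragments 19 rose and 1 fell (median 0.38, under TMM scaling 0.76). With camera at a preset correlation, the adjusted p was 1.12e-13 for young LINE1 antisense and 1.06e-19 for rRNA and tRNA fragments; with an estimated correlation the p was 0.0280 and 0.00606, adjusted 0.266 and 0.115. No camera call in any comparison, of 147 over 228 list tests, held with the estimated correlation. The fry test, which compares a list with 0 and not with other features, gave an adjusted p of 0.0302 for young LINE1 antisense and 0.0925 for rRNA and tRNA fragments.

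In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 542 of 6202 features passed at birth, 57 higher and 485 lower in Tdrd12+/- Exd1-/-. The median log2 change of all features was -0.22 with library totals and 0.08 with TMM factors, and the split moved with it to 186 higher and 379 lower of 565 under TMM and to 97 higher and 224 lower of 321 with DESeq2. Of the 542, 506 had groups that did not overlap, as did 22.6% of all features, where chance gives 10%. Leaving out 1 library moved the count to between 300 and 865, 24-30 nt reads to 189 and uniquely placed reads to 268.

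As shares of reads, LINE1 antisense reads made up 4.26 ± 0.138% of 24-30 nt reads in Tdrd12+/- Exd1-/- newborns and 8.28 ± 0.197% in Tdrd12+/- Exd1+/- (SD, n = 3 each), and LINE1 sense reads 3.99 ± 0.178% and 4.54 ± 0.124%. Reads of 24-30 nt outside structural RNA classes, the size range of piRNAs, made up 7.98 ± 1.93% and 13.0 ± 1.82% of all reads. Adenine at position 10, the mark of secondary piRNAs made by the ping-pong cycle, was found in 18.3 ± 5.09% and 27.2 ± 0.613% of 24-30 nt reads, structural RNA included. Replicate 1 of Tdrd12+/- Exd1-/- stood apart in it, at 12.5% against 20.8% and 21.7%, and was the richest in tRNA (26.6% against 17.98% and 8.17%); among LINE1 antisense reads alone the shares were 35.9 ± 1.75% and 51.2 ± 0.657%. tRNA reads made up 17.6 ± 9.24% and 5.47 ± 0.472% of the library. These differences exceeded the spread between replicates without overlap, at an exact two-sided permutation p of 0.10, the smallest that 3 against 3 allows. Uridine at position 1 (62.1 ± 10.8% and 69.1 ± 0.682%), 10-nt overlaps between strands (12.2 ± 1.43% and 14.1 ± 0.404% of overlaps of 1 to 20 nt) and miRNA reads (65.7 ± 3.90% and 71.2 ± 4.20%) overlapped between groups, at exact permutation p of 0.20, 0.20 and 0.30. The same replicate was low in the first, at 49.7% against 67.7% and 69.0%. The 10-nt overlaps of LINE1 reads, at 13.6 ± 1.38% and 14.1 ± 1.19%, overlapped between groups too (p 0.70). Among transposon reads alone, uridine at position 1 was more frequent in Tdrd12+/- Exd1-/-, with 80.3 ± 0.738% against 69.9 ± 0.142% of LINE1 antisense and 82.95 ± 0.263% against 77.9 ± 0.279% of LTR sense reads of 24-30 nt. LINE1 sense and LTR antisense reads were higher in it too, each without overlap at the smallest exact p.

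**Figure D1:**
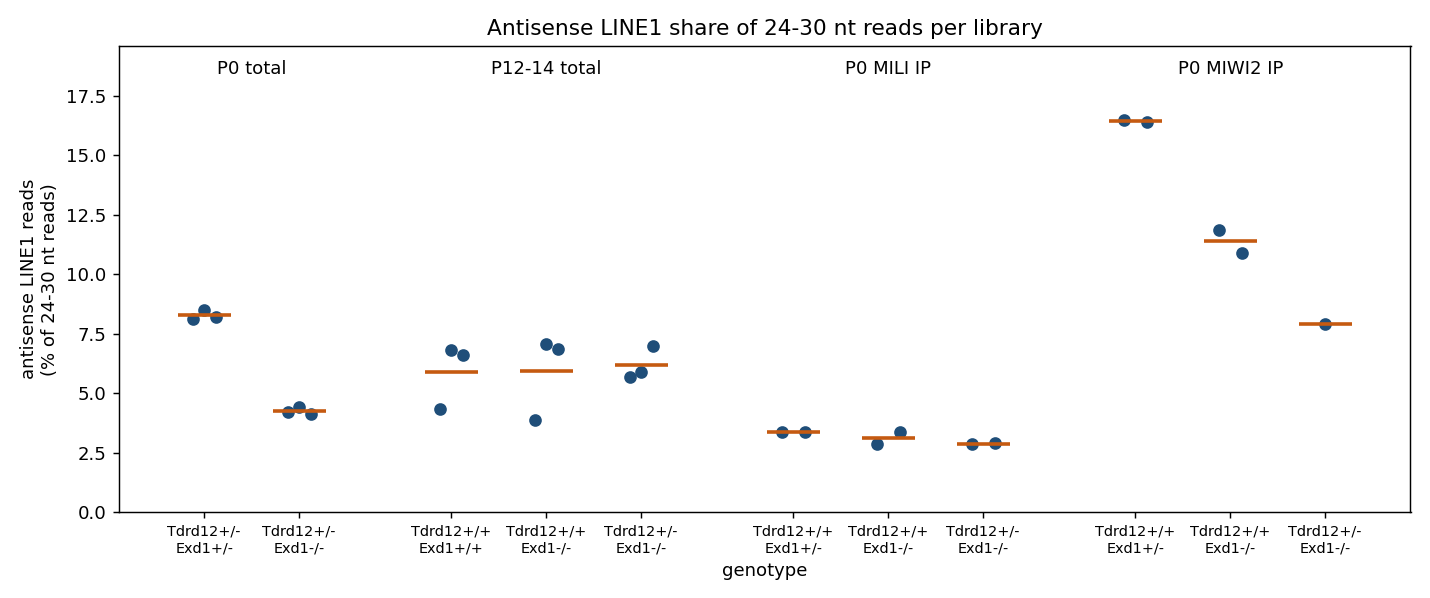
Share of antisense LINE1 reads among 24-30 nt reads outside structural RNA classes (%, y axis) by genotype (x axis) in the total and IP sets. Points are libraries and bars are group means. In newborn total libraries the means were 8.28% in Tdrd12+/- Exd1+/- and 4.26% in Tdrd12+/- Exd1-/-.

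At 12 to 14 days, when spermatocytes enter meiosis, the Tdrd12+/+ Exd1-/- libraries were set against the wild type (n = 3 each). Among the features that rose, Snhg5 sense (chromosome 9, 88521052 to 88522897) averaged 907 ± 612 cpm against 13.8 ± 0.669 (SD), a log2 change of 6.03 ± 0.80 (SE; adjusted p 0.00772), and turned lower among uniquely placed reads (-0.44). A230103J11Rik antisense rose by 5.19, Rpl3 (chromosome 15, 80077781 to 80083406) by 5.10 and Snhg12 by 4.46. Among 24-30 nt reads the calls of A230103J11Rik, Snhg12 and Snhg5 were lost (0.80, 0.87 and 0.82). The libraries were meant to hold 19 to 40 nt. Over 40 nt were 33341 of 36654, 20673 of 24691 and 60474 of 63563 Rpl3 sense reads in Tdrd12+/+ Exd1-/-, against 4 of 1669, 11 of 1565 and 78 of 1530 in the wild type. For Snhg5 sense these were 10424 of 10865, 6507 of 6936 and 18159 of 18553, against 5 of 229, 3 of 237 and 16 of 263. Among the features that fell were Ets1 antisense (-4.67 ± 0.99, adjusted p 0.0280), Dph5 sense (-1.93) and RLTR13D3A1 antisense (-1.91). Each of these rested on a choice: Ets1 lost its call when any library but Tdrd12+/+ Exd1-/- replicate 1 was left out (-4.94 to -4.11). Dph5 turned higher among uniquely placed reads (0.18), where RLTR13D3A1 was no longer called (-0.55). Of the transposons followed in every comparison, MMERVK10C-int sense fell (-1.13 ± 0.21, adjusted p 0.00539), with the call lost under TMM scaling (-0.71), and L1Md_A, L1Md_T and IAPEz-int passed on neither strand.

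No young LINE1 sense feature of 6 passed in Tdrd12+/+ Exd1-/- at 12 to 14 days (0 adjusted over the list alone), and 1 antisense feature of 6 fell. Members also fell among older LINE1 elements (33 sense, with 73 not passing, 42 of 112 antisense with 1 rising), IAP (11 of 25 sense, 3 of 23 antisense), other ERVK (8 and 4 of 20), MuLV and other ERV1 (7 of 21 and 4 of 20), ERVL and MaLR (28 of 55 and 17 of 54) and SINE elements (3 of 31 on each strand). The same libraries differed in albumin (at most 0.124 cpm in mutants, 0.707 to 39.6 in wild type). Reads over 40 nt did too (1.37% to 4.09%, against at most 0.00459%). Against wild-type replicate 1 alone (least albumin, most unannotated reads) L1Md_A sense was 0.62, not -0.30. Most of these calls went with the scaling. Under TMM (edgeR), 1 older LINE1 sense, 0 older LINE1 antisense and 0 IAP features on either strand fell. Of 63 rRNA and tRNA fragments 25 rose and 8 fell (median 0.37), and 4 of 16 let-7, 2 of 18 pluripotency and germ cell and 4 of 15 other testis cell miRNA features rose. The 20 meiotic miRNA features had 8 falling and 12 not passing (9 passing adjusted over the list alone); 1 fell under TMM. The camera p with estimated correlation was 0.0303 for rRNA and tRNA fragments (adjusted 0.544), against an adjusted 2.65e-22 at the preset one. For young LINE1 sense the median (-0.32) and mean (-0.24) were below 0 while camera, which compares with the other features, pointed up (adjusted p 0.412). Under TMM both were above 0 (0.11 and 0.18).

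In the edgeR test 3174 of 17705 features passed in this comparison, 328 higher and 2846 lower. The median log2 change was -0.41, a shift that TMM factors removed (0.00), and with it the direction: 479 higher and 114 lower of 593 under TMM, and 527 higher of 660 with DESeq2. Groups did not overlap for 3110 of the 3174 and for 38.7% of all features, against 10% by chance. Leaving out 1 library moved the count to between 749 and 4907. It was 73 with 24-30 nt reads, 1411 with uniquely placed reads, 1182 in a fit of the 2 groups alone, 105 without the 2 wild-type libraries richest in albumin reads and 5589 without the libraries richest in unannotated reads.

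In Tdrd12+/- Exd1-/- testes of the same age, sense reads of young LINE1 elements were higher than in the wild type (n = 3 each). L1Md_A sense averaged 6170.1 ± 607 cpm against 2024 ± 888 (SD), a log2 change of 1.61 ± 0.28 (SE; adjusted p 0.00967), and the call was lost without Tdrd12+/- Exd1-/- replicate 3 (1.53). L1Md_T sense rose (1.18 ± 0.21, adjusted p 0.00724), a call not every alternative kept. Antisense reads (adjusted p 0.440 and 0.493), IAPEz-int and MMERVK10C-int did not pass. A930015D03Rik sense (chromosome 17, 35994504 to 36038174) fell to 0.322 ± 0.150 from 34.7 ± 5.30 cpm (-6.71 ± 0.40). Dph5 (-1.96), Ptchd2 (-1.69) and ORR1A1-int antisense reads (-1.52) fell too, Dph5 turning higher among uniquely placed reads (0.36). The largest rises were those of Rpl17 (2.65 ± 0.48), AI314180 antisense (2.42), Rpl13 (2.22) and Zfos1 (2.12). The Rpl17 call was lost without any 1 of the wild-type libraries (2.62 to 2.72) or without Tdrd12+/- Exd1-/- replicate 1 (2.84), and the Rpl13 call without any library but Tdrd12+/- Exd1-/- replicate 3 (1.80 to 2.38). Young LINE1 sense features rose in 3 of 6 cases (5 adjusted over the list alone; median 1.00; camera p with estimated correlation 0.0241, adjusted 0.459) and no antisense feature of 6 passed. Older LINE1 elements rose in 3 sense (103 not passing) and 2 of 112 antisense features. Retroviral lists held only falling calls, in 2 of 25 IAP sense, 1 of 23 IAP antisense, 3 and 1 of 20 other ERVK, 1 of 21 and 2 of 20 MuLV and other ERV1, and 11 of 55 and 5 of 54 ERVL and MaLR features. Of 63 rRNA and tRNA fragments 14 rose and 6 fell, 1 of 16 let-7 and 1 of 31 SINE sense features rose, and no SINE antisense or other miRNA list member passed.

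The edgeR test passed 609 of 17705 features in this comparison, 190 higher and 419 lower, with groups that did not overlap in all 609 and in 29.8% of all features (10% by chance). The median log2 change was -0.18; with TMM 260 were higher and 185 lower of 445, with TMM over miRNA features 125 and 317 of 442, and with DESeq2 321 and 182 of 503. Without 1 library the count was 157 to 647. It was 95 with 24-30 nt reads, 315 with uniquely placed reads, 1745 with the 2 groups alone, and 61 and 2465 without the libraries richest in albumin or in unannotated reads.

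Tdrd12+/- Exd1-/- was compared with Tdrd12+/+ Exd1-/-, animals with 1 and 2 Tdrd12 copies, both without EXD1 (n = 3 each). Young LINE1 sense reads were higher with 1 Tdrd12 copy: L1Md_A sense by 1.91 ± 0.28 (6170.1 ± 607 against 1647 ± 181 cpm; adjusted p 0.0126), L1Md_T sense by 1.51 and L1Md_Gf sense by 1.94. The L1Md_T call passed in every set of libraries but not under every alternative. L1Md_A passed only in the full set and without Tdrd12+/+ Exd1-/- replicate 1 (otherwise 1.82 to 1.96). So did L1Md_Gf (else 1.72 to 1.96), lost under TMM too (1.69). B1_Mur1 sense rose by 1.90 ± 0.15 but turned lower among 24-30 nt reads (-0.17). A930015D03Rik fell again (-6.18 ± 0.39), as did Snord96a (-2.23), Rpl21 (-1.47) and mir-299a (-1.21). Leaving out any 1 Tdrd12+/- Exd1-/- library ended the calls of Snord96a (-2.41 to -2.04), Rpl21 (-1.71 to -1.36) and mir-299a (-1.27 to -1.11). Without Tdrd12+/+ Exd1-/- replicate 3 those of Rpl21 (-1.10) and mir-299a (-1.04) ended too, as did Rpl21 without replicate 1 (-1.50) and mir-299a without replicate 2 (-1.05). No IAPEz-int or MMERVK10C-int feature passed. In the lists, 4 of 6 young LINE1 sense features (5 adjusted over the list alone; median 1.35; camera p 0.0449 (adjusted 0.621) with estimated correlation), 12 older LINE1 sense (94 not passing) and 8 of 112 older LINE1 antisense features were higher; under TMM these were 2, 1 and 0. Another 2 of 25 IAP sense, 2 of 55 ERVL and MaLR sense, 1 of 31 SINE sense, 2 of 20 meiotic miRNA and 4 of 63 rRNA and tRNA features were higher, and 2 of 18 pluripotency and germ cell miRNA features lower. ERVL and MaLR antisense had 2 higher and 1 lower of 54, and the remaining lists had no member that passed. The edgeR test passed 279 of 17705 features, 249 higher and 30 lower, with no overlap in all 279 and in 23.5% of all features (10% by chance). The median was 0.20. The split depended on it, with 19 higher and 34 lower of 53 under TMM, 80 and 14 of 94 with TMM over miRNA features and 66 and 141 of 207 with DESeq2. Without 1 library the count was 15 to 2442, with 24-30 nt reads 10, in a fit of the 2 groups alone 47 and without the libraries richest in unannotated reads 3055.

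LINE1 sense reads made up 4.39 ± 1.46% of 24-30 nt reads in the wild type, 4.76 ± 1.45% in Tdrd12+/+ Exd1-/- and 8.69 ± 1.17% in Tdrd12+/- Exd1-/- at 12 to 14 days (SD, n = 3 each), the last without overlap with either other group (exact two-sided permutation p 0.10 each, the smallest possible). LINE1 antisense shares were 5.92 ± 1.38%, 5.95 ± 1.78% and 6.20 ± 0.685% and overlapped. tRNA reads made up 2.15 ± 0.0951%, 4.50 ± 0.978% and 3.88 ± 0.888% of the libraries and rRNA reads 2.08 ± 0.474%, 4.04 ± 0.876% and 3.16 ± 0.377%, both mutants above the wild type without overlap. Adenine at position 10 was found in 28.6 ± 0.735%, 26.6 ± 0.404% and 26.5 ± 0.0613% of 24-30 nt reads, both mutants below the wild type without overlap.

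At birth, MILI, the PIWI protein of primary piRNAs, was compared between genotypes (n = 2 each), as shares of bound RNA. In Tdrd12+/+ Exd1-/- the satellite GSAT_MM fell from 368 ± 48.6 to 119 ± 32.3 cpm on the sense strand (-1.63 ± 0.21, SE; adjusted p 0.000578) with -1.32 on the antisense strand. Reads of 1700128A07Rik (chromosome 14, 106417187 to 106486520) fell on the sense (-1.57) and antisense strands (-1.49). Slco3a1 antisense rose by 1.78, Sorcs2 sense (chromosome 5, 36017180 to 36398197) by 1.30 and C130046K22Rik sense by 1.13. L1Md_A sense came near the threshold (-0.93 ± 0.18, adjusted p 0.0530); no LINE1, IAPEz-int or MMERVK10C-int feature passed. At a minimum mean of 10 cpm all calls were lost. Under TMM C130046K22Rik, Slco3a1 and GSAT_MM antisense were too (0.99, 1.65 and -1.45). Without a Tdrd12+/+ Exd1+/- library C130046K22Rik was 1.08 or 1.19, GSAT_MM antisense -1.23 (replicate 1 out) and 1700128A07Rik antisense -1.24 (replicate 2 out). None of the 19 lists had a member that passed over all features; adjusted over the list alone, 5 of 6 young LINE1 sense features did (median -0.66; camera p 0.0907 with estimated correlation), 2 each of ERVL and MaLR sense and SINE sense, and 1 each of meiotic miRNA and of rRNA and tRNA fragments. In the edgeR test 8 of 25602 features passed, 4 on each side, and 2218 had an unadjusted p under 0.05; TMM gave 1 higher and 8 lower of 9, and DESeq2 2 and 16 of 18. The median log2 change was 0.14, and 36.6% of features did not overlap between groups, against 33.3% by chance. Leaving out 1 library gave 16 to 976.

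In Tdrd12+/- Exd1-/- MILI libraries the same satellite fell from the Tdrd12+/+ Exd1+/- level to 55.2 ± 8.02 cpm sense (-2.73 ± 0.22; antisense -2.99; n = 2 each), as did 1700128A07Rik (sense -2.28, antisense -2.30). Sense reads of young transposons fell: L1Md_A (-0.97 ± 0.18, adjusted p 0.00638), L1Md_T (-0.83) and IAPEz-int (-1.08 ± 0.19, 1167 ± 74.7 against 2466 ± 132 cpm), with IAPEz-int antisense at -0.92. These LINE1 and IAP calls were lost without Tdrd12+/- Exd1-/- replicate 1 (-0.99, -0.85, -1.02 and -0.93) or 2 (-0.95, -0.82, -1.15 and -0.91), and L1Md_T also without Tdrd12+/+ Exd1+/- replicate 2 (-0.76). H2-Q8 antisense (2.27), Sorcs2 (1.90), Pclo antisense (1.82) and Inadl antisense (1.80) rose. Young LINE1 sense features fell in 5 of 6 cases (median -0.83; camera p 0.0556 with estimated correlation), none of 6 antisense did. Other falling members were 1 of 109 older LINE1 sense, 2 of 113 antisense, 3 and 2 of 25 IAP, 2 of 20 other ERVK sense, 5 and 1 of 55 ERVL and MaLR, 2 of 31 SINE on each strand, 1 of 14 let-7, 1 of 17 meiotic miRNA and 3 of 56 rRNA and tRNA features. Under TMM 9 and 11 ERVL and MaLR and 7 rRNA and tRNA features fell. MuLV and other ERV1 sense had 1 rising and 1 falling of 24. For older LINE1 antisense the median (0.23) and mean (0.20) were above 0 and camera pointed down (adjusted p 0.515), and under TMM the median was -0.07. The edgeR test passed 581 of 25602 features, 466 higher and 115 lower, with no overlap in all 581 and in 56.0% of all features (33.3% by chance). The median was 0.29, and other scalings turned the split to 59 higher and 252 lower of 311 (TMM) and 13 and 180 of 193 (DESeq2). Leaving out 1 library gave 25 to 279, a minimum mean of 10 cpm 30 and a fit of the 2 groups alone 3086.

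Between the mutants, 2 MILI features passed, both lower in Tdrd12+/- Exd1-/- than in Tdrd12+/+ Exd1-/-: GSAT_MM antisense (-1.67 ± 0.27, adjusted p 0.0222) and IAPEz-int sense (-1.32 ± 0.19, adjusted p 0.00338). Both calls were lost without either Tdrd12+/- Exd1-/- library (GSAT_MM -1.74 and -1.60, IAPEz-int -1.26 and -1.39). L1Md_A and L1Md_T passed on neither strand, and IAPEz-int sense was the only list member that did, 4 IAP sense, 1 IAP antisense and 4 other ERVK sense features passing adjusted over the list alone. Unadjusted edgeR p was under 0.05 for 1516 of 25602 features, TMM gave 0 calls with 1250 under 0.05, and DESeq2 gave 2; 36.1% of features did not overlap, against 33.3% by chance. Leaving out 1 library gave 0 (684 under 0.05) to 546.

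MIWI2, the nuclear PIWI protein of fetal and newborn germ cells, was compared in the same way (n = 2 for Tdrd12+/+ Exd1+/- and Tdrd12+/+ Exd1-/-). Antisense LINE1 reads fell in Tdrd12+/+ Exd1-/-: L1Md_A antisense averaged 11162 ± 1166 cpm against 15580 ± 421 (SD), a log2 change of -0.48 ± 0.06 (SE; adjusted p 0.00109), while L1Md_T antisense at -0.53 ± 0.13 did not pass (adjusted p 0.129) and passed under TMM (-1.01) and without any single library (-0.67 to -0.40). GSAT_MM fell from 5203 ± 1147 to 713 ± 89.5 cpm on the sense strand (-2.87 ± 0.27, adjusted p 0.0453), with -2.53 on the antisense strand, calls lost without Tdrd12+/+ Exd1-/- replicate 1 (-2.75 and -2.53) or 2 (-3.002 and -2.52). 1700128A07Rik antisense (-2.44 ± 0.21) and Tcte3 antisense (-2.28) fell. IAPEz-int moved apart by strand, with sense reads up from 11038 ± 42.6 to 21949 ± 238 cpm (0.99 ± 0.04) and antisense reads down (-0.23); with DESeq2 the sense change was 0.51 and not called, and the antisense call was lost without Tdrd12+/+ Exd1+/- replicate 2 (-0.23). MMERVK10C-int was higher by 0.45 sense and 0.34 antisense with library totals, but lower under TMM (-0.03 and -0.13). D130009I18Rik (1.88), Sorcs2 (1.82), Aen (1.69) and Rpl23 (1.68) rose.

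In the lists, 5 of 6 young LINE1 antisense features fell in Tdrd12+/+ Exd1-/- MIWI2 (6 adjusted over the list alone; median -0.53, under TMM -1.01; camera p with estimated correlation 0.123, adjusted 0.353) and none of 6 sense features passed (TMM, 3 lower). IAP sense had 15 higher and 1 lower of 25 with library totals but 2 higher and 4 lower under TMM, and IAP antisense 7 and 7 of 25 (TMM, 0 and 11). Falling calls prevailed in ERVL and MaLR (25 of 55 sense with 5 higher, 31 of 55 antisense with 1 higher), SINE (9 of 31 with 1 higher, 13 of 31), MuLV and other ERV1 (9 of 24 with 2 higher, 6 of 24 with 2 higher) and older LINE1 antisense features (25 of 108 with 6 higher). Under TMM none of these was higher, and 33 and 34 ERVL and MaLR, 22 and 26 SINE, 15 and 16 MuLV and other ERV1 and 35 older LINE1 antisense features fell. Older LINE1 sense had 7 higher and 9 lower of 102 (TMM, 24 lower), and other ERVK 8 higher and 3 lower of 20 sense and 4 and 6 of 20 antisense, where TMM gave 0 higher in each. Of the miRNA lists, 2 of 13 meiotic and 2 of 11 other testis cell features rose and no let-7 or pluripotency and germ cell feature did; of 53 rRNA and tRNA fragments 14 rose (TMM, 4). For older LINE1 antisense the median was 0.03, the mean -0.08 and camera pointed down. The edgeR test passed 2670 of 18950 features, 2208 higher and 462 lower, with no overlap in all 2670 and in 62.1% of all features (33.3% by chance). The median log2 change was 0.50 with library totals and 0.03 with TMM, and the split turned to 255 higher and 1099 lower of 1354 (TMM) and 42 and 658 of 700 (DESeq2). Without 1 library the count was 513 to 2747.

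The lone Tdrd12+/- Exd1-/- MIWI2 library was tested on the assumption that it varies like the other groups. Its own spread is unknown, and the values, counts and p-values below describe this 1 library. GSAT_MM stood at 129 cpm against 5203 ± 1147 in Tdrd12+/+ Exd1+/- (-5.34 ± 0.41, adjusted p 0.0242), and 1700128A07Rik was lower on the sense (-3.80) and antisense strands (-3.67). L1Md_A antisense was lower (-1.01 ± 0.08, 7719 cpm; adjusted p 2.79e-05) and L1Md_T antisense at -1.06 ± 0.16 missed the threshold (adjusted p 0.0504). It passed under TMM (-1.78). IAPEz-int sense was higher by 0.72 with library totals, 0.00 under TMM and -0.02 with DESeq2. MMERVK10C-int was higher by 0.18 and 0.39 with library totals and lower under TMM (-0.54 and -0.33). The largest fold values on the higher side were those of miRNAs, mir-871 (3.23 ± 0.54), mir-292b antisense (3.16), mir-744 (2.62) and mir-465c-1 (2.46). Such gains, here and below, cannot be told apart from this library's higher miRNA share. List members followed: 10 of 13 meiotic, 9 of 15 pluripotency and germ cell and 4 of 11 other testis cell miRNA features were higher, and 0 of 12 let-7 features passed (edgeR; 2 higher under TMM) despite a median of 2.23. Young LINE1 features were lower in 4 of 6 sense and 5 of 6 antisense cases (antisense median -1.10; camera p 0.0752 with estimated correlation). With library totals the older LINE1 lists had 13 higher and 15 lower of 102 sense and 10 and 26 of 108 antisense features. IAP had 7 and 1 of 25 sense and 1 and 11 of 25 antisense, and other ERVK 5 and 4 of 20 and 3 and 10 of 20. MuLV and other ERV1 had 0 and 11 of 24 and 3 and 6 of 24, ERVL and MaLR 10 and 24 of 55 and 6 and 27 of 55, and SINE 6 and 7 of 31 and 4 and 10 of 31. Under TMM no feature of these lists was higher, IAP sense turned to 14 lower and SINE to 22 and 24 lower. Of 53 rRNA and tRNA fragments 13 were higher with library totals, against 4 higher and 4 lower under TMM. The edgeR test passed 4512 of 18950 features, 4063 of them higher, with no overlap in all 4512 and in 87.9% of all features (66.7% by chance for 1 against 2). The median was 0.75 and fell to 0.04 under TMM, where 407 were higher and 1204 lower of 1611; DESeq2 gave 54 and 763 of 817.

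Against Tdrd12+/+ Exd1-/-, the same library had lower Wiz antisense (-1.71 ± 0.27) and sense (-1.22) reads, 1700128A07Rik sense (-1.54) and MusHAL1 antisense (-1.26), and higher Csnk2a2 antisense (2.99 ± 0.32), mir-741 (2.93), mir-292b antisense (2.63) and Kat2b (2.19). L1Md_A antisense was lower (-0.53 ± 0.08, adjusted p 0.0152), as were IAPEz-int sense (-0.27) and MMERVK10C-int sense (-0.27), both lost as calls under TMM (-0.51 and -0.52). L1Md_T passed on neither strand. The calls of Wiz (-1.36 antisense, -0.86 sense), Kat2b (1.62) and MMERVK10C-int sense (-0.20) were lost without Tdrd12+/+ Exd1-/- replicate 2. Young LINE1 features were lower in 3 of 6 sense and 4 of 6 antisense cases (antisense median -0.54; camera p 0.144 with estimated correlation). Lower members also numbered 8 of 102 older LINE1 sense, 17 of 108 antisense, 5 of 25 IAP antisense, 3 of 20 other ERVK on each strand, 1 of 24 MuLV and other ERV1 sense, 7 and 3 of 55 ERVL and MaLR and 1 of 53 rRNA and tRNA features, and IAP sense had 1 higher and 2 lower of 25. Higher members were 5 of 13 meiotic, 1 of 15 pluripotency and germ cell and 1 of 11 other testis cell miRNA features and 1 of 31 SINE sense features. Under TMM 8 meiotic, 6 pluripotency and germ cell, 4 other testis cell and 3 of 12 let-7 features were higher, and 5 sense and 6 antisense young LINE1 but no IAP sense features lower. The edgeR test passed 141 of 18950 features, 68 higher and 73 lower, with no overlap in all 141 and in 74.3% of all features (66.7% by chance). The median was 0.22, TMM gave 94 higher and 78 lower of 172, DESeq2 6 and 38 of 44, and leaving out 1 library 38 to 89.

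LINE1 antisense reads made up 16.5 ± 0.0748% of 24-30 nt MIWI2 reads in Tdrd12+/+ Exd1+/-, 11.4 ± 0.659% in Tdrd12+/+ Exd1-/- (SD, n = 2) and 7.93% in the lone Tdrd12+/- Exd1-/- library, and LINE1 sense reads 5.10 ± 0.00666%, 5.43 ± 0.318% and 4.46%. Adenine at position 10 was found in 45.0 ± 0.486%, 36.2 ± 0.418% and 34.9%, and uridine at position 1 in 71.4 ± 1.29%, 78.0 ± 0.0630% and 78.0%. Of LINE1 overlaps of 1 to 20 nt between strands, 14.0 ± 0.464%, 12.01 ± 0.260% and 12.2% were 10 nt long. miRNA reads made up 1.59 ± 1.01%, 2.53 ± 1.08% and 5.93% of all MIWI2 reads. In the MILI IP, LINE1 sense shares were 3.43 ± 0.0510%, 2.76 ± 0.556% and 2.49 ± 0.0920% and antisense shares 3.38 ± 0.0221%, 3.13 ± 0.362% and 2.89 ± 0.0434% (n = 2 each), with 10-nt overlaps at 8.46 ± 0.0723%, 9.13 ± 0.0529% and 8.80 ± 0.170% of all overlaps.

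**Figure D2:**
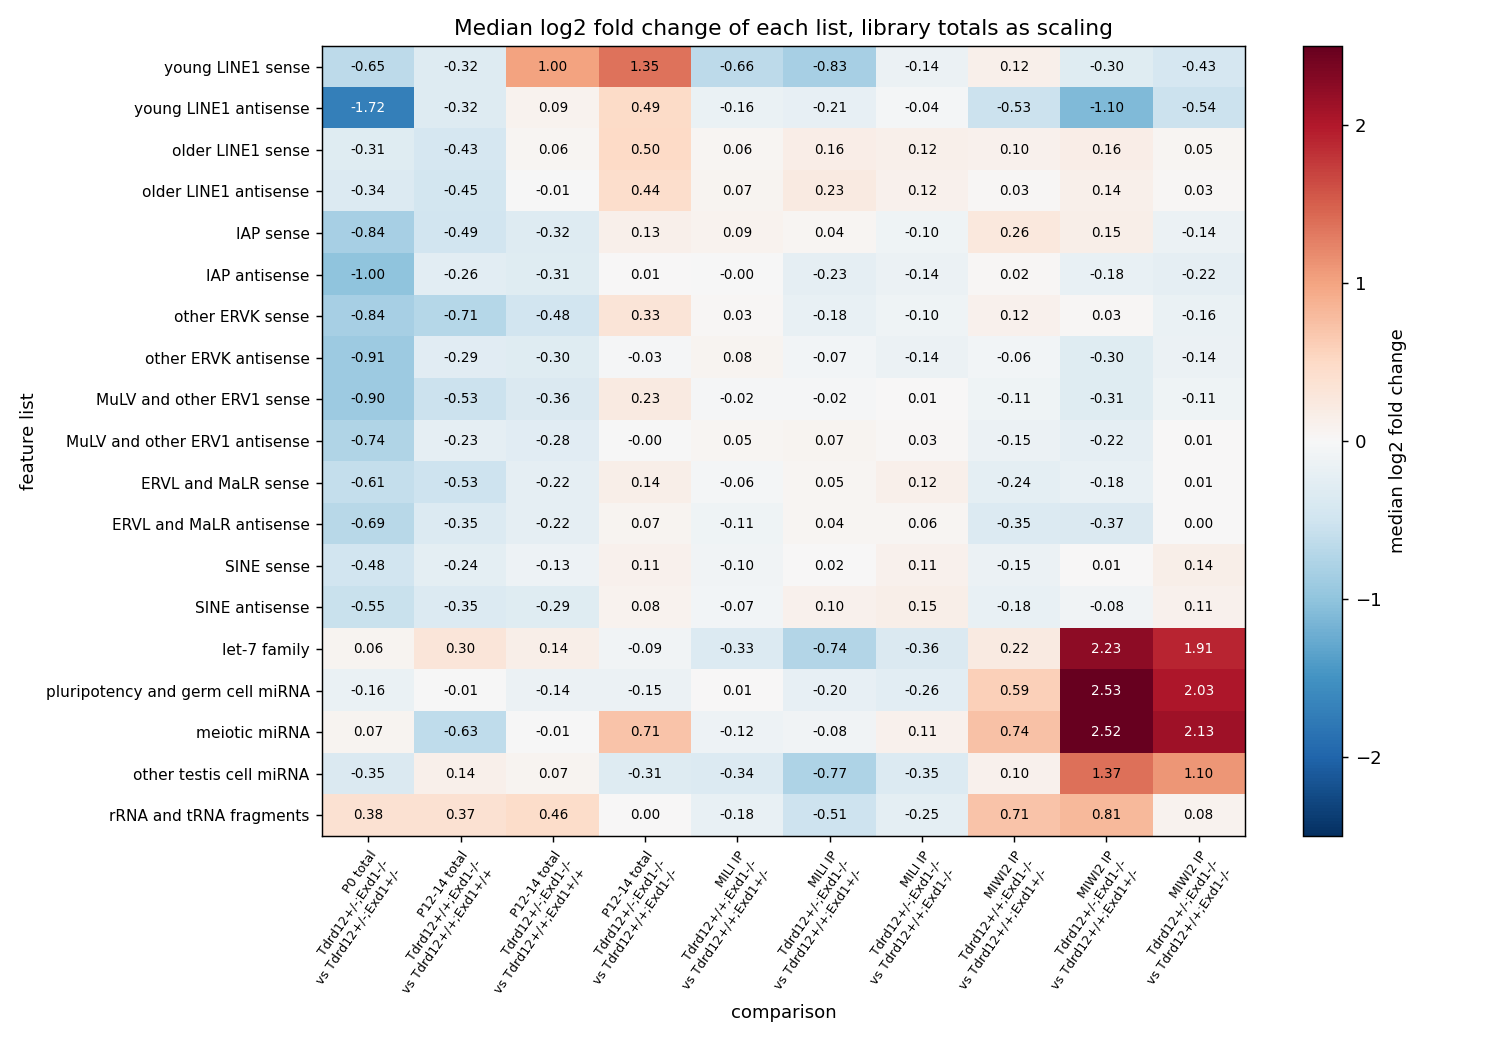
Median log2 fold change (colour and printed value) of each feature list (y axis) in each comparison (x axis), scaled by library totals. Young LINE1 antisense stood at -1.72 in newborn total libraries.

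An interaction term in edgeR tested whether MIWI2 and MILI responded differently. For Tdrd12+/+ Exd1-/- against Tdrd12+/+ Exd1+/-, 4 of 27580 features passed, 2 in each direction, and 2493 had an unadjusted p under 0.05; TMM gave 10, all lower in MIWI2, and DESeq2 19, all lower. For Tdrd12+/- Exd1-/-, 103 passed, 74 with the change higher in MIWI2 and 29 lower; TMM gave 20 and 63 of 83 and DESeq2 90 and 115 of 205. Its MIWI2 side is the lone library. Young LINE1 antisense features supplied 5 of the 29 lower ones, of 6 in the list (median -0.84; camera p 0.0289 (adjusted 0.110) with estimated correlation), and IAPEz-int sense passed in the other direction (1.80 ± 0.22). Without 1 library the first count was 1 to 288 and the second 28 or more.

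On the Rosa26-pi construct, minus-strand reads were rarer in Exd1+/- and Exd1-/- than in Exd1+/+. In the MILI IP they made up 29.3% of 18531 reads in Exd1+/+ (95% Clopper-Pearson interval 28.7 to 30.0), 24.8% of 45484 in Exd1+/- (24.4 to 25.2) and 15.2% of 49381 in Exd1-/- (14.8 to 15.5). In the MIWI2 IP the shares were 19.8% of 56070 (19.4 to 20.1), 16.6% of 24812 (16.1 to 17.1) and 13.9% of 38934 (13.5 to 14.2). Relative to Exd1+/+, the Exd1-/- share was 0.517 (0.501 to 0.533) in MILI and 0.702 (0.681 to 0.723) in MIWI2. Without the position with the most reads, the MIWI2 ratio was 0.796 (0.755 to 0.838) in Exd1+/- and 0.762 (0.728 to 0.797) in Exd1-/-, with intervals that overlap. The commonest plus-strand read in Exd1+/+ was 28 nt long in MIWI2 (27.9% of the strand) and 27 nt in MILI (27.2%), and uridine at position 1 was found in 67.2%, 68.1% and 70.8% of MIWI2 plus-strand reads. With 1 library per genotype, the intervals cover counting error only and the spread between animals is unknown.

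**Figure D3:**
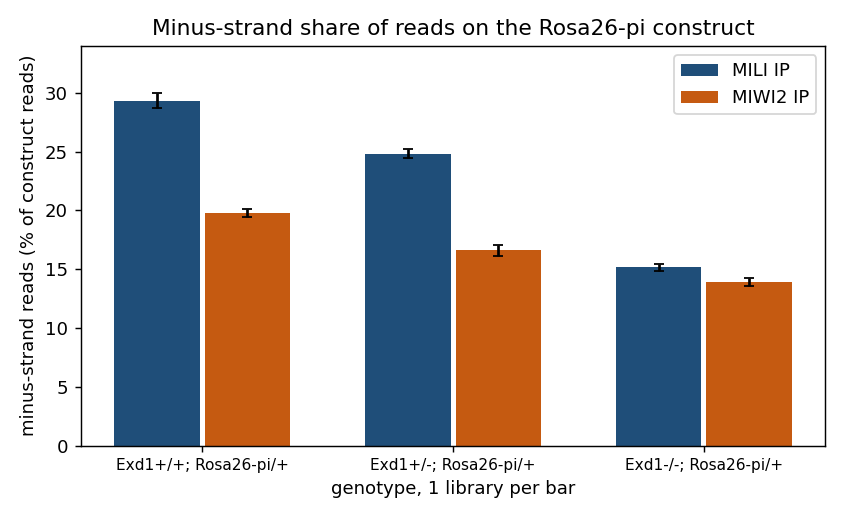
Minus-strand reads as a percentage of all reads on the Rosa26-pi construct (y axis, from 0) by Exd1 genotype (x axis); each bar is 1 library and the error bars are 95% Clopper-Pearson intervals. MILI shares were 29.3%, 24.8% and 15.2%.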

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

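Of the tests in this part, the one comparing satellite with albumin reads was chosen only after the result was seen. The test of a difference between the MIWI2 and the MILI response gave 4 features for Tdrd12+/+ Exd1-/- and 103 for Tdrd12+/- Exd1-/-, the latter resting on 1 MIWI2 library. The values below are log2 changes in MIWI2 minus those in MILI, each relative to Tdrd12+/+ Exd1+/-, for the features of the rule that passed. For Tdrd12+/+ Exd1-/- they are L1MDa antisense at -1.54 and tRNA-Ile-ATT at 2.29. For Tdrd12+/- Exd1-/- they describe the lone MIWI2 library relative to MILI, whose own variation is unknown, so that a difference between the responses is not shown; for antisense LINE1 reads they lie below 0: L1MDa -2.57, L1VL2 -1.56, MusHAL1 -1.47, L1VL4 -1.30, L1Md_Gf -1.20, L1_Mus2 -1.13, L1_Mus3 -1.01, L1_Mus1 -1.004, L1_Mur1 -0.94 and L1Md_T -0.78. GSAT_MM sense lies below 0 likewise (-2.60), while IAPEz-int sense (1.80) and IAPLTR2a2_Mm sense (1.48) lie above 0. So do reads of Rps20 (1.87), Mrpl42 (1.80), Cox4i1 (1.69), Rpl23 (1.57) and Mt2 (1.43), the miRNAs mir-292b antisense (3.13), mir-202 (2.82), mir-465c-1 (2.72), mir-22 (2.39) and mir-151 (2.36), and tRNA-Ile-ATT (2.86). No group held 4 or more libraries, so that no single library was tested as far from its group.

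GSAT_MM reads were lower without EXD1 in newborn total RNA (17.2, 28.5 and 31.04 against 505, 449.4 and 623 cpm), in MILI and in MIWI2. A few abundant sequences are argued against: without the top 10, the weakest log2 ratio was -1.54 and no libraries overlapped. RNA of other cells, as marked by albumin, is argued against for the IPs. Control IPs held 0 to 3 albumin reads and mutant IPs 0 to 7. For total RNA this source stays open. The GSAT_MM to albumin ratio (floor 3 reads), at least 147 times higher in control IP than newborn total controls, cannot decide. Mutant IPs lie higher too. A difference in satellite DNA stays open: GSAT_MM reads outside 24-30 nt were lower too (-3.86), and genotype cannot be told apart from it. A loss of satellite piRNAs with EXD1 stays open, not tested by itself.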

How the results depend on the processing

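The alternatives chosen only after the result was seen are library sizes without tRNA and rRNA reads, reads of at most 40 nt, and leaving out the 2 wild-type libraries richest in albumin reads or the libraries richest in unannotated reads; all others were planned. No paired analysis was possible because nothing ties a library to one of another genotype. Comparisons are named by group: newborn for Tdrd12+/- Exd1-/- against Tdrd12+/- Exd1+/- total RNA; single for Tdrd12+/+ Exd1-/- and compound for Tdrd12+/- Exd1-/-, each against its control; mutants for compound against single; juvenile for 12 to 14 days; interaction for MIWI2 minus MILI. Of the counts and other values that answer a comparison, 61 alternative values stayed within the set limits (a count within 1.5 times the main one) and 118 moved. Of the single values followed (features, lists, shares), 2950 kept direction and call, 539 lost a call, 130 gained one, 224 turned direction and 37 without a test moved. For every value printed here the cause was not tested, except that a leave-one-out fit has fewer libraries, a minimum mean of 10 cpm tests fewer features, and TMM and DESeq2 centre the typical feature at 0. A group of 1 library left by a leave-one-out fit is assumed to vary like the other groups. Alternative alignments, other rules for sequences with several positions and other repeat annotations were not run, since the tables hold 1 position and 1 annotation per sequence. For the lone Tdrd12+/- Exd1-/- MIWI2 library no leave-one-out value of its own and no fit of 2 groups alone exist.

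The main counts of called features were 542 (newborn), 3174 (juvenile single), 609 (juvenile compound), 279 (juvenile mutants), 8 (MILI single), 581 (MILI compound), 2 (MILI mutants), 2670 (MIWI2 single), 4512 (MIWI2 compound), 141 (MIWI2 mutants), 4 (interaction single) and 103 (interaction compound). With TMM it was 593 (juvenile single), 53 (juvenile mutants), 311 (MILI compound), 0 (MILI mutants), 1354 (MIWI2 single), 1611 (MIWI2 compound) and 10 (interaction single). With TMM over miRNA features it was 360 (newborn) and 94 (juvenile mutants). With DESeq2 it was 321 (newborn), 660 (juvenile single), 18 (MILI single), 193 (MILI compound), 700 (MIWI2 single), 817 (MIWI2 compound), 44 (MIWI2 mutants), 19 (interaction single) and 205 (interaction compound). With no filter it was 1305 (juvenile compound), 1064 (juvenile mutants), 98 (MILI single), 1217 (MILI compound), 38 (MILI mutants), 258 (MIWI2 mutants), 66 (interaction single) and 323 (interaction compound). With a minimum mean of 10 cpm it was 1268 (juvenile single), 284 (juvenile compound), 0 (MILI single), 30 (MILI compound), 0 (MILI mutants), 1138 (MIWI2 single), 1479 (MIWI2 compound), 56 (MIWI2 mutants), 2 (interaction single) and 42 (interaction compound). With 24-30 nt reads it was 189 (newborn), 73 (juvenile single), 95 (juvenile compound), 10 (juvenile mutants), 15 (MILI single), 10 (MILI mutants), 22 (interaction single) and 242 (interaction compound). With uniquely placed reads it was 268 (newborn), 1411 (juvenile single), 315 (juvenile compound), 148 (juvenile mutants), 368 (MILI compound), 0 (MILI mutants), 1714 (MIWI2 single), 1984 (MIWI2 compound), 1 (interaction single) and 67 (interaction compound). With only the 2 groups compared it was 1182 (juvenile single), 1745 (juvenile compound), 47 (juvenile mutants), 1 (MILI single) and 3086 (MILI compound). With library size without tRNA and rRNA reads it was 1760 (juvenile single). With reads of at most 40 nt it was 1 (MILI mutants). Leaving out the 2 wild-type libraries richest in albumin reads gave 105 (juvenile single) and 61 (juvenile compound). Leaving out the libraries richest in unannotated reads gave 5589 (juvenile single), 2465 (juvenile compound) and 3055 (juvenile mutants). Leaving out each library in turn gave counts of 300 to 865 (newborn), 749 to 4907 (juvenile single), 157 to 647 (juvenile compound), 15 to 2442 (juvenile mutants), 16 to 976 (MILI single), 25 to 279 (MILI compound), 0 to 546 (MILI mutants), 513 to 2747 (MIWI2 single), 38 to 89 (MIWI2 mutants), 1 to 288 (interaction single) and 28 to 152 (interaction compound). Where edgeR gave a count of 0, the features with an unadjusted p under 0.05 numbered 618 (MILI single, a minimum mean of 10 cpm), 1250 (MILI mutants, TMM), 413 (MILI mutants, a minimum mean of 10 cpm), 1355 (MILI mutants, uniquely placed reads) and 684 (MILI mutants, without Tdrd12+/- Exd1-/- replicate 1); DESeq2 called 18 (MILI single) and 2 (MILI mutants).

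Called features that kept direction and call under every alternative in which they were tested were, newborn, IAPEz-int antisense, L1Md_A antisense, L1Md_T antisense, GSAT_MM antisense, GSAT_MM sense, Alb sense and tRNA-Met-i sense. Juvenile compound kept ORR1A1-int antisense, A930015D03Rik sense and Ptchd2 sense. Juvenile mutants kept A930015D03Rik sense. MILI compound kept GSAT_MM antisense, GSAT_MM sense, 1700128A07Rik sense and Sorcs2 sense. MIWI2 single kept L1Md_A antisense, 1700128A07Rik antisense, Aen sense, D130009I18Rik sense, Sorcs2 sense and Tcte3 antisense. MIWI2 compound kept L1Md_A antisense, GSAT_MM antisense, GSAT_MM sense, 1700128A07Rik antisense, 1700128A07Rik sense, mir-292b antisense, mir-465c-1 sense and mir-744 sense. MIWI2 mutants kept L1Md_A antisense and MusHAL1 antisense.

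With TMM, log2 changes that turned direction were, in the juvenile single comparison, IAPEz-int sense from -0.21 to 0.20, L1Md_A antisense from -0.28 to 0.13, L1Md_A sense from -0.30 to 0.13, L1Md_T antisense from -0.38 to 0.0353, L1Md_T sense from -0.34 to 0.0846, MMERVK10C-int antisense from -0.29 to 0.13 and Tdrd12 sense from -0.41 to 6.72e-04. Juvenile mutants had Exd1 sense from 0.24 to -0.0194. MILI single had Exd1 sense from 0.0301 to -0.11. MILI compound had MMERVK10C-int antisense from 0.22 to -0.0827. MIWI2 single had Exd1 sense from 0.36 to -0.11, L1Md_A sense from 0.14 to -0.34, L1Md_T sense from 0.11 to -0.37, MMERVK10C-int antisense from 0.34 to -0.13 and MMERVK10C-int sense from 0.45 to -0.0260. MIWI2 compound had Exd1 sense from 0.11 to -0.61, MMERVK10C-int antisense from 0.39 to -0.33 and MMERVK10C-int sense from 0.18 to -0.54. MIWI2 mutants had IAPEz-int antisense from 0.0834 to -0.16 and MMERVK10C-int antisense from 0.0509 to -0.19. Interaction single had Exd1 sense from 0.33 to -0.0433, IAPEz-int antisense from 0.24 to -0.16, MMERVK10C-int antisense from 0.12 to -0.27, MMERVK10C-int sense from 0.16 to -0.23 and Tdrd12 sense from 0.35 to -0.0194. Interaction compound had Exd1 antisense from 0.23 to -0.20, Exd1 sense from 0.33 to -0.12, MMERVK10C-int antisense from 0.18 to -0.28 and MMERVK10C-int sense from 0.36 to -0.0880.

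With DESeq2, log2 changes that turned direction were, in the juvenile single comparison, IAPEz-int sense from -0.21 to 0.21, L1Md_A antisense from -0.28 to 0.14, L1Md_A sense from -0.30 to 0.13, L1Md_T antisense from -0.38 to 0.0396, L1Md_T sense from -0.34 to 0.0903, MMERVK10C-int antisense from -0.29 to 0.14 and Tdrd12 sense from -0.41 to 0.00759. Juvenile mutants had Exd1 sense from 0.24 to -0.0104. MILI single had Exd1 sense from 0.0301 to -0.10. MILI compound had MMERVK10C-int antisense from 0.22 to -0.0746. MIWI2 single had Exd1 sense from 0.36 to -0.12, L1Md_A sense from 0.14 to -0.35, L1Md_T sense from 0.11 to -0.38, MMERVK10C-int antisense from 0.34 to -0.14 and MMERVK10C-int sense from 0.45 to -0.0316. MIWI2 compound had Exd1 antisense from 0.71 to -0.0272, Exd1 sense from 0.11 to -0.63, IAPEz-int sense from 0.72 to -0.0210, MMERVK10C-int antisense from 0.39 to -0.35 and MMERVK10C-int sense from 0.18 to -0.56. MIWI2 mutants had IAPEz-int antisense from 0.0834 to -0.18 and MMERVK10C-int antisense from 0.0509 to -0.21. Interaction single had Exd1 sense from 0.33 to -0.0667, IAPEz-int antisense from 0.24 to -0.18, MMERVK10C-int antisense from 0.12 to -0.29, MMERVK10C-int sense from 0.16 to -0.26 and Tdrd12 sense from 0.35 to -0.0608. Interaction compound had Exd1 antisense from 0.23 to -0.21, Exd1 sense from 0.33 to -0.13, MMERVK10C-int antisense from 0.18 to -0.28 and MMERVK10C-int sense from 0.36 to -0.0962.

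With 24-30 nt reads, log2 changes that turned direction were, in the newborn comparison, L1MD3 sense from 2.14 to -0.32 and L1Md_T sense from 0.0606 to -0.78. Juvenile single had IAPEz-int sense from -0.21 to 0.0485 and L1Md_A antisense from -0.28 to 0.00152. Juvenile mutants had B1_Mur1 sense from 1.90 to -0.17 and IAPEz-int antisense from -0.0305 to 0.0755. MIWI2 compound had Exd1 sense from 0.11 to -0.17.

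With uniquely placed reads, log2 changes that turned direction were, in the newborn comparison, L1MD3 sense from 2.14 to -0.42 and L1Md_T sense from 0.0606 to -0.29. Juvenile single had Dph5 sense from -1.93 to 0.18 and Snhg5 sense from 6.03 to -0.44. Juvenile compound had Dph5 sense from -1.96 to 0.36 and L1Md_T antisense from 0.25 to -0.0616. Juvenile mutants had IAPEz-int antisense from -0.0305 to 0.0271. MILI single had Exd1 sense from 0.0301 to -0.00224, L1Md_A antisense from -0.37 to 0.0677, L1Md_T antisense from -0.24 to 0.17 and L1Md_T sense from -0.73 to 0.0378. MILI compound had L1Md_A antisense from -0.43 to 0.16 and L1Md_T antisense from -0.28 to 0.20. MILI mutants had L1Md_A antisense from -0.0581 to 0.0898, L1Md_T antisense from -0.0454 to 0.0279 and MMERVK10C-int antisense from -0.00367 to 0.0970. MIWI2 single had L1Md_T sense from 0.11 to -0.0362. MIWI2 compound had Exd1 sense from 0.11 to -0.12 and MMERVK10C-int sense from 0.18 to -0.17. MIWI2 mutants had IAPEz-int antisense from 0.0834 to -0.23 and MMERVK10C-int antisense from 0.0509 to -0.15. Interaction single had IAPEz-int antisense from 0.24 to -0.0430, L1Md_T sense from 0.83 to -0.0740 and MMERVK10C-int antisense from 0.12 to -0.10. Interaction compound had IAPEz-int antisense from 0.77 to -0.0398, L1Md_A sense from 0.70 to -0.28, L1Md_T sense from 0.62 to -0.49, MMERVK10C-int antisense from 0.18 to -0.35 and MMERVK10C-int sense from 0.36 to -0.12.

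By leaving out the 2 wild-type libraries richest in albumin reads, log2 changes that turned direction were, in the juvenile single comparison, L1Md_A antisense from -0.28 to 0.17, L1Md_A sense from -0.30 to 0.62, L1Md_T antisense from -0.38 to 0.0117 and L1Md_T sense from -0.34 to 0.24.

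By leaving out the libraries richest in unannotated reads, log2 changes that turned direction were, in the juvenile mutants comparison, IAPEz-int antisense from -0.0305 to 0.90 and MMERVK10C-int antisense from -0.13 to 0.13.

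Leaving out each library in turn, features turned direction within these ranges of log2 change (main value in parentheses): newborn, L1Md_T sense -0.0572 to 0.22 (0.0606). The juvenile single ranges were L1Md_A sense -0.60 to 0.0251 (-0.30). The juvenile mutants ranges were IAPEz-int antisense -0.38 to 0.90 (-0.0305) and MMERVK10C-int antisense -0.26 to 0.13 (-0.13). The MILI single ranges were Exd1 antisense -0.19 to 0.63 (0.29), Exd1 sense -0.13 to 0.21 (0.0301), IAPEz-int sense -0.0697 to 0.50 (0.25) and Tdrd12 sense -0.36 to 0.18 (-0.0808). The MILI mutants ranges were Exd1 antisense -0.15 to 0.67 (0.19), L1Md_A antisense -0.30 to 0.23 (-0.0581), L1Md_A sense -0.27 to 0.24 (-0.0377), L1Md_T antisense -0.18 to 0.10 (-0.0454), L1Md_T sense -0.35 to 0.19 (-0.11) and MMERVK10C-int antisense -0.16 to 0.17 (-0.00367). The MIWI2 single ranges were L1Md_T sense -0.0163 to 0.22 (0.11). The MIWI2 mutants ranges were Exd1 antisense -0.25 to 0.18 (-0.0542) and MMERVK10C-int antisense -0.0138 to 0.12 (0.0509). The interaction single ranges were Exd1 antisense -0.0261 to 1.12 (0.48), L1Md_A antisense -0.35 to 0.19 (-0.11), MMERVK10C-int antisense -0.0326 to 0.30 (0.12) and MMERVK10C-int sense -0.0574 to 0.42 (0.16). The interaction compound ranges were Exd1 antisense -0.27 to 0.88 (0.23).

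Of the 228 list tests, 147 passed with camera at the preset correlation, 166 under TMM, 0 with an estimated correlation and 23 with fry. With TMM the lists that turned direction, with their adjusted p from camera to the TMM fit, were, newborn, older LINE1 sense 0.815 to 0.965. Juvenile single had IAP antisense 0.972 to 0.956 and SINE antisense 0.972 to 0.770. Juvenile mutants had SINE sense 0.891 to 0.944. MILI mutants had older LINE1 sense 0.998 to 0.287 and older LINE1 antisense 0.998 to 0.287. MIWI2 single had IAP sense 0.693 to 0.0403 and pluripotency and germ cell miRNA 0.693 to 0.688. Interaction single had IAP sense 0.820 to 0.0353. Interaction compound had IAP sense 0.220 to 0.240. With fry the lists that turned direction, with their adjusted p from camera to fry, were, newborn, pluripotency and germ cell miRNA 0.516 to 0.106 and meiotic miRNA 0.116 to 0.931. Juvenile single had young LINE1 sense 0.412 to 0.431, young LINE1 antisense 0.972 to 0.0997, IAP antisense 0.972 to 0.0182 and SINE sense 0.320 to 0.0209. Juvenile compound had SINE sense 0.168 to 0.741, pluripotency and germ cell miRNA 0.727 to 0.546 and meiotic miRNA 0.168 to 0.949. Juvenile mutants had IAP sense 0.809 to 0.142, IAP antisense 0.181 to 0.519, other ERVK antisense 0.187 to 0.511, MuLV and other ERV1 antisense 0.442 to 0.297, ERVL and MaLR antisense 0.614 to 0.387, SINE antisense 0.187 to 0.262 and rRNA and tRNA fragments 0.00490 to 0.813. MILI single had older LINE1 sense 0.114 to 0.956, older LINE1 antisense 0.455 to 0.942, IAP sense 0.665 to 0.956, other ERVK antisense 0.378 to 0.956, MuLV and other ERV1 antisense 0.636 to 0.956 and pluripotency and germ cell miRNA 0.450 to 0.956. MILI compound had older LINE1 sense 0.129 to 0.698, older LINE1 antisense 0.515 to 0.692 and MuLV and other ERV1 antisense 0.101 to 0.765. MILI mutants had MuLV and other ERV1 sense 0.102 to 1.000, MuLV and other ERV1 antisense 0.184 to 0.953, ERVL and MaLR sense 0.579 to 0.805, ERVL and MaLR antisense 0.232 to 0.855, SINE sense 0.450 to 0.805, SINE antisense 0.998 to 0.805 and meiotic miRNA 0.233 to 0.953. MIWI2 single had young LINE1 sense 0.321 to 0.458, older LINE1 sense 4.47e-05 to 0.458, other ERVK sense 0.0845 to 0.278, let-7 family 0.693 to 0.687, pluripotency and germ cell miRNA 0.693 to 0.629 and other testis cell miRNA 0.412 to 0.630. MIWI2 compound had older LINE1 sense 1.52e-07 to 0.386 and IAP sense 0.0420 to 0.138. MIWI2 mutants had older LINE1 sense 0.00177 to 0.843, SINE sense 0.940 to 0.0988, SINE antisense 0.430 to 0.228 and rRNA and tRNA fragments 0.152 to 0.780. Interaction single had older LINE1 sense 0.00105 to 0.816, IAP antisense 0.0334 to 0.903 and other ERVK sense 0.349 to 0.748. Interaction compound had other ERVK sense 0.316 to 0.653 and SINE sense 0.0215 to 0.809.

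Differences in class shares (percentage points, or nt) turned with distinct sequences in place of reads: miRNA, newborn, from -5.49 to 0.499, uridine at position 1, newborn, from -6.99 to 3.11, piRNA-window reads, juvenile single, from -2.60 to 0.953, miRNA, juvenile single, from -1.12 to 0.187 and uridine at position 1, juvenile single, from -3.24 to 0.433. So did miRNA, juvenile compound, from -1.35 to 0.0715, uridine at position 1, juvenile compound, from -1.89 to 0.825, miRNA, MILI single, from -3.005 to 0.0148, LINE1 sense, MIWI2 single, from 0.334 to -0.179 and tRNA, MIWI2 compound, from -0.200 to 0.0165. With reads of 19-40 nt as the denominator the share differences that turned were miRNA, juvenile single, from -1.12 to 0.237 and piRNA-window reads, juvenile mutants, from -0.0339 to 0.260. With a window of 25-31 nt the share differences that turned were mean window length (nt), juvenile compound, from -0.00328 to 0.0324. Leave-one-out share differences, juvenile single, were -7.87 to 0.574 for piRNA-window reads (-2.60), -3.84 to 3.90 for miRNA (-1.12), -0.764 to 1.05 for LINE1 antisense (0.0295) and -0.442 to 1.21 for LINE1 sense (0.371). Those of juvenile compound were -0.515 to 0.726 for LINE1 antisense (0.279) and -0.0104 to 0.00593 for mean window length (nt) (-0.00328). Those of juvenile mutants were -3.21 to 5.24 for piRNA-window reads (-0.0339), -5.25 to 2.49 for miRNA (-0.236), -0.774 to 0.817 for LINE1 antisense (0.249), -0.490 to 4.44 for uridine at position 1 (1.35) and -0.319 to 0.0550 for adenine at position 10 (-0.0879).

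The Rosa26-pi minus-strand share of Exd1+/- in MILI relative to Exd1+/+ (0.846) was 0.877 among 24-30 nt reads and 0.795 per plus-strand read. For Exd1-/- in MILI (0.517) it was 0.493 among 24-30 nt reads and 0.430 per plus-strand read. For Exd1+/- in MIWI2 (0.840) it was 0.796 leaving out the position with the most reads and 0.808 per plus-strand read. For Exd1-/- in MIWI2 (0.702) it was 0.762 leaving out the position with the most reads and 0.654 per plus-strand read.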

Other observations

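Of the tests in this part, those of long fragments, of long reads in newborn libraries and of albumin among the wild-type libraries were chosen only after the result was seen. Reads over 40 nt made up 1.98%, 1.37% and 4.09% of the Tdrd12+/+ Exd1-/- libraries at 12 to 14 days, 0.435%, 0.724% and 0.290% of Tdrd12+/- Exd1-/- and 0.00443%, 0.000968% and 0.00459% of the wild type, in libraries meant to hold 19 to 40 nt RNA. They gave 86.2% of the summed gain of the 22 Snhg, Gas5, Rpl and Rps genes called higher in Tdrd12+/+ Exd1-/-, and most of the gain in 14 of the 22. Of the 102 such genes tested, 25 were called lower. For the gain of these genes, fragments longer than 40 nt are a candidate explanation. For the other 306 features called higher they are argued against as the main one, since they gave 15.4% of the summed gain, and most of the gain in 47 features. Loss of Exd1 stays open, since newborn libraries gave no single answer for reads over 40 nt of the 22 genes. In total RNA all Tdrd12+/- Exd1-/- libraries lay above all Tdrd12+/- Exd1+/- ones (314, 353 and 392 against 48.8, 218 and 313 cpm). MILI libraries overlapped, with 59947 and 42219 cpm in Tdrd12+/+ Exd1-/- and 30146 and 43762 in Tdrd12+/- Exd1-/- against 44331 and 37182 in Tdrd12+/+ Exd1+/- (first over last mean, 1.25). In MIWI2, size-selected to 24 to 30 nt, they were lower without EXD1 (5.97, 6.11 and 12.97 against 13.2 and 48.4 cpm). Of all newborn total reads, 0.357%, 0.368% and 0.454% were over 40 nt in Tdrd12+/- Exd1-/- and 0.0206%, 0.0543% and 0.140% in Tdrd12+/- Exd1+/-, so library preparation may differ between genotypes at both ages; the labels give no batch.

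Newborn Tdrd12+/- Exd1+/- libraries held 2564 reads of 27 listed hepatocyte genes, against 94 in Tdrd12+/- Exd1-/-. RNA of hepatocytes is a candidate explanation. Of 25 listed genes with 10 or more reads, 24 were higher in every Tdrd12+/- Exd1+/- than in every Tdrd12+/- Exd1-/- library. So were 100% of the 11 not looked at before. Afp did not follow (36 against 39 reads). Of the listed genes, 21 also had reads in Tdrd12+/- Exd1-/-, and no sorting that would remove hepatocytes is described. Alb, abundant in these cells, had 302, 333 and 388 control reads. At 12 to 14 days the wild-type libraries held 0.707, 18.2 and 39.6 albumin cpm, a range of 56.0-fold, and the mutant libraries at most 0.124. Of the 27 listed genes, all with enough reads at that age, 8 were higher in every wild-type than in every mutant library, as were 3 of the 11 not looked at before; Afp was not. A link with the loss of Exd1 cannot be told apart from tissue carried over, since all mutant libraries lie below all wild-type ones in albumin.

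For each comparison of 3 with 3 libraries, features were also called for the 9 other splits (10 in all, too few for a share under 0.05). In each, only the real split reached the real count. The genotypes gave 542 features at birth and the highest other split 0; at 12 to 14 days they gave 3174 against 3 for Tdrd12+/+ Exd1-/- and the wild type, 609 against 0 for Tdrd12+/- Exd1-/- and the wild type, and 279 against 0 between the mutants.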
